A study of Mus musculus with 2 samples.

How the data were processed

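Isolated colonic crypt cells of C57BL/6 mice aged 4 weeks were profiled with 10x Genomics single-cell RNA sequencing, in 1 library per genotype, each a pool of cells from 3 mice. The deposited values are raw counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger, version 3.0.0 per the submitters' processing notes and 3.1.0 per the file headers. The processing notes also list Seurat 3. The genome build, annotation release and kit end are not given in the sources used here. Barcodes had been called as cells before deposition, with no barcode under 500 UMIs. The matrices listed 31053 genes, of which 99.9% have their Ensembl ID in GENCODE M21 (GRCm38), used here for coordinates only. The control library held 111239295 UMIs in 10181 barcodes, with a median of 2478 genes and 3.74% mitochondrial UMIs per barcode. The Mettl14_cKO library held 89729527 UMIs in 9225 barcodes, with medians of 1379 genes and 6.30%. M14 in the labels was read as Mettl14.

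Cells with at least 500 genes and under 25% mitochondrial UMIs were kept, which removed 1027 control (10.1%) and 2100 Mettl14_cKO barcodes (22.8%). Scrublet, as run in scanpy 1.11.5, was applied to each library, and cells with a score of at least 0.25 were removed as doublets, 77 control (0.841%) and 53 Mettl14_cKO cells (0.744%). That score was set after the data were seen, because the automatic threshold marked 2 and 1 cells. The kept cells had 108723963 and 85680951 UMIs, with medians of 10037 and 6253.5 per cell. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours, Leiden clustering at resolution 1 gave 34 clusters of both libraries together, with no integration. Mitochondrially encoded, ribosomal protein and gasdermin genes, Mettl14, Xist, Tsix and 733 genes of the Y chromosome were left out of the variable genes. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

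Clusters were named from fixed markers of 13 classes. A class needed at least 3 markers among the 50 leading genes of a cluster and no other class with more among the 10 leading genes. Shallow clusters also needed a marker of the class among the 10 leading genes. Leading genes were ranked by fold over the other cells of the same library. These rules for clusters were set after the data were seen. Markers included Lgr5, Ascl2 and Smoc2 (stem), Mki67, Top2a and Pcna (cycling), Muc2, Fcgbp and Mptx1 (goblet), Car1, Aqp8, Sult1a1 and Ly6g (colonocyte), Chga and Neurod1 (enteroendocrine), Dclk1 and Trpm5 (tuft), Cd3e and Nkg7 (T or NK), Cd79a and Jchain (B or plasma), and Lyz2 and S100a8 (myeloid). Fibroblast, endothelial, glia and erythroid markers were searched in the same way. Clusters with at least 90% of their epithelial-like cells from the control are called control-majority clusters. Other clusters counted as unnamed epithelial where Epcam reached 50% of the median of the named epithelial clusters.

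Counts were summed over the cells of a class and scaled by the total UMIs of the class (CPM) with exact Poisson intervals, and shares of cells have exact binomial intervals. With 1 library per genotype no test was made, and no gene was called changed. The size of a gene is log2 of the ratio of CPM, Mettl14_cKO over control, each plus 1. The main comparison used the mean size over the cycling-like, goblet-like, colonocyte-like and enteroendocrine-like classes, each with at least 100 cells in both libraries. Eligible genes had at least 50 CPM in 1 library and 10 UMIs. Mitochondrially encoded, ribosomal, haemoglobin, immunoglobulin, T cell receptor, Xist, Tsix and Y chromosome genes were not eligible, nor were genes over 5 times higher in a non-epithelial class. The Y chromosome genes beyond the 4 with reported levels (Ddx3y, Eif2s3y, Kdm5d and Uty) were left out after a first run had named Gm28588. The 12 highest and 12 lowest genes with the same sign in each class were named, and the 4 highest and 4 lowest in each class, with Mettl14 and the gasdermin C genes always named. Ratios against 0 UMIs are lower bounds from a floor of 3 counts. Tuft-like cells had too few cells for ranking.

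The 32 gene lists held 506 genes, 1 of them absent from the matrices. They covered gasdermins, m6A writers, m6A erasers and readers, colonic stem cell genes, Wnt targets, the Notch pathway, S phase, G2 and M phase, p53 targets, intrinsic apoptosis, and pyroptosis and necroptosis. Immune lists covered TNF and NF-kB targets, interferon response, MHC class II, MHC class I and antimicrobial defence. Epithelial lists covered mucus genes, ion and water transport, mature colonocyte genes, tight junctions, enteroendocrine hormones, fetal-like genes, distal Hox genes and small intestine markers. Metabolic and stress lists covered mitochondrially encoded genes, nuclear oxidative phosphorylation, fatty acid oxidation, glycolysis, cholesterol synthesis, the unfolded protein and integrated stress response, NRF2 targets with metallothioneins, and dissociation genes. A member was measured with at least 20 UMIs and counted as higher or lower at 1.5-fold. Percentiles describe the list median among 10000 random lists of the same size, matched in 25 bins of expression. For shares of cells with a UMI, each cell was thinned to 1700 UMIs, the 10th percentile of epithelial-like cells rounded down.

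The markers, gene lists and filter on genes and mitochondrial share were fixed before the data were examined. So were all alternatives but those named below as added. The rule for naming genes was fixed then too, except for the further Y chromosome genes left out after a first run. The steps were tested on simulated data with 200 changed genes among 31053. Sizes had medians of -1.996, -1.015, -0.61, 0.56, 0.96 and 1.96 for true folds of 0.25, 0.5, 0.667, 1.5, 2 and 4. All 66 genes changed 4-fold were the 66 most extreme, and the intervals held the truth for 95.35% of 2345 unchanged genes. A list of 20 genes changed 2-fold reached percentile 100 and an unchanged list 41.34. Thinning gave 20 of 1000 cells with a UMI where 18.51 were expected. This covers counting error for the comparison of the 2 libraries, not differences between animals.

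Alternatives were no doublet removal, a lenient filter (200 genes, 50% mitochondrial), a strict filter (1000 genes, 10%), resolutions of 0.5 and 2, and Mettl14_cKO cells named by their nearest control cells. Others were median-of-ratios scaling, thinned cells, a pseudocount of 10 CPM, list members with at least 100 UMIs, all kept cells as denominator, and no thinning or thinning to 850 UMIs. Cells with at least 5000 UMIs alone, and subtraction of the mean UMIs per T or NK-like cell, were added after the data were seen. The subtraction says nothing about genes that T or NK-like cells express themselves, such as Isg15, Psmb8, Psmb9, Pclaf, Ncf4 and B2m.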

Results

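Single-cell RNA was sequenced from isolated colonic crypt cells of C57BL/6 mice aged 4 weeks. The control library came from mice with floxed Mettl14 alleles, which the labels write as M14(f/f). The Mettl14_cKO library came from floxed mice that also carried Villin-Cre, a recombinase made in gut epithelial cells. Cells of 3 mice were pooled for each genotype before capture, so each genotype had 1 library. No test, error between animals or check against a replicate was possible, and all intervals are 95% intervals that cover counting error only or, for list medians, the spread of the members. The control library held 10181 cell barcodes with 111239295 UMIs, a median of 9085 per barcode. The Mettl14_cKO library held 9225 barcodes with 89729527 UMIs, a median of 3872. After filtering and doublet removal 9077 control and 7072 Mettl14_cKO cells were kept, of which 8702 and 6052 were epithelial-like. The genotype could not be separated from the sex of the mice. Xist, the RNA of the inactive X chromosome, had 0.0644 CPM in the control library and 312 CPM in the Mettl14_cKO library. A sum of 4 Y-linked genes had 103 and 0.0700 CPM in the same order.

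The first comparison asked whether the targeted gene was lower. Mettl14 (ENSMUSG00000028114), which encodes a subunit of the m6A methyltransferase of RNA, was not lower in epithelial-like cells as a whole. It had 514 UMIs, or 4.76 CPM (4.36 to 5.19), in the control and 417 UMIs, or 5.06 CPM (4.58 to 5.56), in the Mettl14_cKO library, a ratio of 1.06 (0.930 to 1.21). In cycling-like cells it had 5.58 and 6.66 CPM, in goblet-like cells 4.64 and 4.15, in colonocyte-like cells 4.10 and 3.55, and in enteroendocrine-like cells 6.46 and 6.71. In T or NK-like cells, where Villin-Cre does not act, it had 5.15 and 4.02 CPM from 4 UMIs each. Mettl14 lies on chromosome 3 from 123368297 to 123386108 on the minus strand (GRCm38, GENCODE M21; the build used for the deposited counts is not given in the sources used here). Which exons were floxed was not stated, and a tag outside the deleted part would remain, so this value checks neither the deletion nor the labels. In cells thinned to a common depth the log2 ratio of 0.07 was -0.32, with an interval that includes both (-0.99 to 0.20).

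The series title names GsdmC, and the second comparison asked how much of its RNA the epithelium held. The gasdermin C genes, members of the family of pore-forming gasdermin proteins, were lower in the Mettl14_cKO library in every class compared. Summed over the 4 genes, epithelial-like cells had 36014 UMIs in the control and 2347 in the Mettl14_cKO library, or 334 and 28.5 CPM, an 11.7-fold lower level (11.2 to 12.2). Of these classes colonocyte-like cells held the highest level, 907 and 124 CPM (7.32-fold lower, 6.73 to 7.98), across different clusters (6, 10, 13, 22, 28 and 32 in the control, 18 in the Mettl14_cKO library). In the control-majority clusters alone it was 907 and 359 CPM in colonocyte-like cells (2.52-fold lower, 2.25 to 2.83), and 4.29-fold lower in cycling-like (3.51 to 5.29) and 5.49-fold lower in goblet-like cells (3.58 to 8.89). The Mettl14_cKO library had only 52, 101 and 116 such cells, in that order. They were picked by their likeness to control cells, so these folds do not correct those of whole classes. Over whole classes the sum was 198 and 51.0 CPM in cycling-like cells (3.88-fold, 3.65 to 4.13) and 36.3 and 4.40 CPM in goblet-like cells (8.24-fold, 7.001 to 9.75). In enteroendocrine-like cells it was 81.2 and 2.88 CPM, the latter from 6 UMIs (28.2-fold, 12.7 to 77.9). T or NK-like cells, which are not epithelial, had 48.9 and 6.03 CPM from 38 and 6 UMIs. The sum in epithelial-like cells was lower in the Mettl14_cKO library under all 11 other settings. Gsdmc4 carried most of the sum in the control, with 240 and 11.6 CPM in epithelial-like cells (20.7-fold, 19.4 to 22.1). Gsdmc2 had 73.8 and 10.5 CPM (7.04-fold, 6.56 to 7.56), Gsdmc3 had 20.1 and 6.38 (3.15-fold, 2.86 to 3.47), and Gsdmc had 2 and 0 UMIs. These pooled folds include the different mix of classes in each library. Within cycling-like, goblet-like and colonocyte-like cells the folds were 6.93, 14.001 and 9.72 for Gsdmc4, 2.64, 6.06 and 5.06 for Gsdmc2, and 1.46, 2.96 and 2.84 for Gsdmc3. With each cell thinned to 1700 UMIs, 42.1% of 2221 control colonocyte-like cells (40.0 to 44.2) and 4.91% of 346 in the Mettl14_cKO library (2.89 to 7.75) had a Gsdmc4 UMI. The unthinned shares were 68.6% and 15.6%, at median depths of 10703 and 9592.5 UMIs. In T or NK-like cells, with median depths of 1630.5 and 1938.5 UMIs, the thinned shares were 4.65% (8 of 172) and 0 of 248, which allows up to 1.48%. The genes lie side by side on the minus strand of chromosome 15, from 63775968 (Gsdmc) through Gsdmc2 (from 63824346) and Gsdmc3 (from 63857724) to 63912297 (Gsdmc4). Of the 60-base words in the last 500 bases of their transcripts, 23.4% (Gsdmc), 27.9% (Gsdmc2), 32.0% (Gsdmc3) and 2.49% (Gsdmc4) also occur in other genes, so the sum is firmer than the values of single genes.

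**Figure D1:**
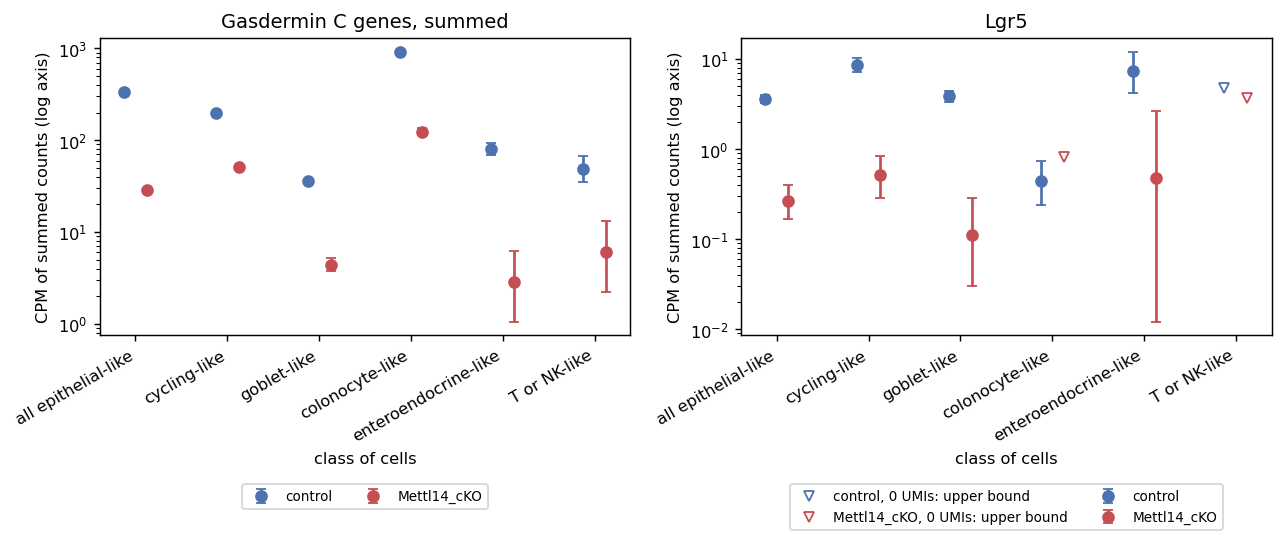
CPM of the summed gasdermin C genes (left) and of Lgr5 (right) in each class of cells, on log axes, for the control library (blue) and the Mettl14_cKO library (red); points are sums of counts with 95% Poisson intervals, and open triangles are upper bounds where a class had 0 UMIs. The gasdermin C sum was 907 CPM in control colonocyte-like cells and 124 CPM in those of the Mettl14_cKO library.

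Lgr5, the receptor that marks intestinal stem cells and is named in the series title, was lower in the Mettl14_cKO library, and so was the stem cell gene Smoc2. In epithelial-like cells Lgr5 (ENSMUSG00000020140) had 386 UMIs in the control and 22 in the Mettl14_cKO library, or 3.58 (3.23 to 3.95) and 0.267 CPM (0.167 to 0.404), a 13.4-fold lower level (8.73 to 21.7). Within cycling-like cells, mostly of clusters 3 and 5 in the control and 7, 8 and 19 in the Mettl14_cKO library, it was 16.8-fold lower (9.85 to 30.9), from 139 and 15 UMIs. Within goblet-like cells, also of different clusters, it was 34.9-fold lower (13.4 to 129), from 199 and 4 UMIs. In the control-majority clusters alone it was 2.04-fold lower in cycling-like (1.01 to 4.84) and 3.09-fold lower in goblet-like cells (1.19 to 11.5). The Mettl14_cKO library had 8 and 4 UMIs there, from 101 and 116 cells picked by their likeness to control cells. At 1700 UMIs per cell, 52 of 7870 control epithelial-like cells (0.661%, 0.494 to 0.866) and 1 of 5419 in the Mettl14_cKO library (0.0185%, up to 0.103) had an Lgr5 UMI, a difference of -0.642 percentage points (-0.847 to -0.464). The share expected over all random draws was 0.598% and 0.0225%. The common depth left out 832 and 633 shallower cells, and the unthinned shares were 3.40% and 0.297% at median depths of 10397 and 8701 UMIs. No T or NK-like cell had an Lgr5 UMI, 0 of 172 and 0 of 248, which allows shares of up to 2.12% and 1.48%. These limits lie above the epithelial shares, so this background check could not exclude free RNA at that level.

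Smoc2, a secreted matrix protein of crypt base cells, had 11.4 and 3.89 CPM (2.93-fold lower, 2.59 to 3.33), with thinned shares of 2.13% and 0.535% (unthinned 10.0% and 3.37%; T or NK-like 0.581% and 0.403%). Ascl2, a transcription factor of intestinal stem cells, went the other way over all epithelial-like cells, with 11.5 and 18.8 CPM and thinned shares of 1.75% (1.48 to 2.07) and 2.57% (2.16 to 3.02). Its unthinned shares were 7.47% and 11.8%, and 1 of 172 and 0 of 248 T or NK-like cells had a thinned UMI. Within cycling-like cells its thinned shares were 5.11% and 4.42%, and its mean log2 ratio over classes was -0.79. Of 20 colonic stem cell genes measured, 7 were at least 1.5-fold lower (Lgr5 -1.96, Smoc2 -1.68, Cdca7 -1.34), 1 was higher (Olfm4 2.08, a secreted glycoprotein) and 12 lay between. The list median was -0.33 on the log2 scale (interval -0.70 to 0.04), at the 1.09 percentile of 10000 matched random lists. It turned to between 0.04 and 0.09 under 3 of 12 other settings. Within cycling-like cells 4 members were higher and 5 lower (median -0.20, percentile 10.4). The medians were -0.32 in goblet-like (percentile 3.49), -0.36 in colonocyte-like (percentile 20.8) and -0.78 in enteroendocrine-like cells (percentile 0). Of 15 Wnt target genes 4 were lower, 0 higher and 11 between (median -0.40, percentile 0.42), led by Lgr5 and the cyclin gene Ccnd1 (-1.01). That median had an interval of -0.69 to 0.08, and was -0.05 with no doublets removed, -0.09 with the strict filter, -0.04 at resolution 2 and -0.14 in thinned cells. Lgr5, Ascl2, Sp5, Cd44, Ephb2, Ephb3 and Tnfrsf19 belong to both the stem cell and the Wnt list, so the medians of these lists are not separate results. Of 10 Notch pathway genes 6 were lower, 0 higher and 4 between (median -0.66, percentile 0.04), led by Nrarp (-1.50) and the receptor gene Notch1 (-1.43). The Notch median had an interval of -1.43 to 0.06 and ran from -0.87 to -0.25 under other settings. By class it was -0.33 in cycling-like, -0.65 in goblet-like, -0.59 in colonocyte-like and -1.47 in enteroendocrine-like cells. No cluster met the marker rule for stem-like cells, which leaves open how many lay in other clusters. The lenient cell filter gave such a cluster, with 36 of 9612 control and 1231 of 7445 Mettl14_cKO cells, or 0.375% and 16.5%. Under that filter unnamed epithelial cells were 16.4% in the control and 4.31% in the Mettl14_cKO library. The stem-like shares therefore depend on which clusters met the marker rule and cannot be read as more stem cells.

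Colonocyte-like cells, the absorptive cells of the colon, made up less of the epithelium in the Mettl14_cKO library. They were 2333 of 8702 epithelial-like cells in the control (26.8%, 25.9 to 27.8) and 360 of 6052 in the Mettl14_cKO library (5.95%, 5.37 to 6.57). Cycling-like cells were 21.3% (20.4 to 22.1) and 34.1% (32.9 to 35.3), and mucus-secreting goblet-like cells 45.5% (44.4 to 46.5) and 41.5% (40.3 to 42.8). Hormone-secreting enteroendocrine-like cells were 2.59% (2.26 to 2.94) and 6.43% (5.82 to 7.08), and chemosensory tuft-like cells 0.563% (49 cells) and 0.727% (44 cells). Epithelial clusters that met no marker rule, a rule whose folds were set within each library after the data were seen, held 3.31% and 11.3%. Immune cells made up more of the Mettl14_cKO library. All non-epithelial-like cells were 375 of 9077 kept cells (4.13%, 3.73 to 4.56) and 1020 of 7072 (14.4%, 13.6 to 15.3). Myeloid-like cells were 9 (0.0992%) and 431 (6.09%), B or plasma-like cells 6 (0.0661%) and 197 (2.79%), and T or NK-like cells 360 (3.97%) and 392 (5.54%). Fibroblast-like, endothelial-like, glia-like and erythroid-like clusters were not found, though the lenient filter gave an erythroid-like cluster with 24 control cells (0.239%) and 2 Mettl14_cKO cells.

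The class shares rest on clusters that parted by library. Of 28 epithelial clusters 23 took at least 90% of their cells from 1 library. They held 13486 of 14754 epithelial-like cells (91.4%), so a cluster may be a library and not a type. Most cycling-like cells lay in clusters 3 and 5 in the control and in 7, 8 and 19 in the Mettl14_cKO library. Most goblet-like cells lay in 0, 1, 9, 14, 17 and 29 against 2, 4 and 16, and most colonocyte-like cells in 6, 10, 13, 22, 28 and 32 against 18. Enteroendocrine-like cells shared clusters 15 and 27, and tuft-like cells cluster 31. Unnamed epithelial cells lay in 20 against 11 and 30, T or NK-like cells in 12 against 12 and 23. All values within classes compare these clusters unless control-majority clusters are named. Other settings turned the cycling-like and goblet-like differences round: a stricter cell filter put cycling-like cells at 34.7% and 18.1% and unnamed epithelial cells at 1.35% and 28.4%. The colonocyte-like share was lower in the Mettl14_cKO library in all 8 other settings, by -14.0 to -21.7 percentage points.

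**Figure D2:**
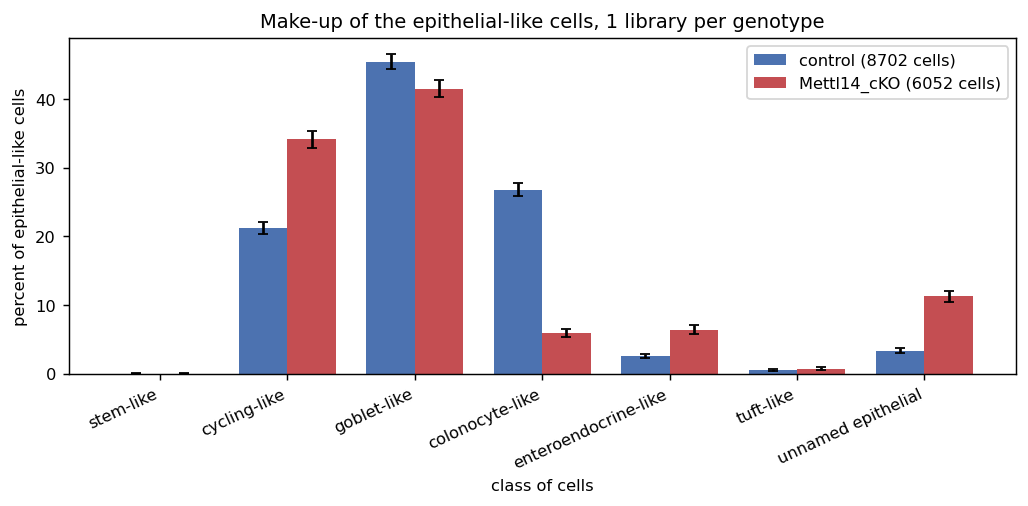
Percent of epithelial-like cells in each class, for the control library (blue, 8702 cells) and the Mettl14_cKO library (red, 6052 cells); bars are shares with exact 95% binomial intervals. Colonocyte-like cells were 26.8% and 5.95% of the epithelial-like cells.

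The main comparison asked which genes differed within the epithelial-like classes. Of the 12 genes with the highest mean ratio over the 4 classes, several encode protease inhibitors and secreted or surface proteins. Slpi, the secretory leukocyte protease inhibitor, led with a mean log2 ratio of 6.64. It had 0.620 and 562 CPM in cycling-like cells (907-fold higher, 493 to 1891) and 16.2 and 1542 CPM in goblet-like cells (95.0-fold, 88.7 to 102). Spink1, a trypsin inhibitor (5.03), had 347 and 14832.5 CPM in goblet-like cells (42.8-fold, 42.1 to 43.4), and Serpina10, another protease inhibitor (5.27), had 2.09 and 77.2 CPM there. Ly6g, a surface protein best known from neutrophils and one of the markers used to name colonocytes (5.16), had 3.66 and 1139 CPM in colonocyte-like cells (311-fold, 259 to 377). Ubd, a ubiquitin-like modifier (4.78), had 0.473 and 474 CPM there (1001-fold, 606 to 1792). Msln, the surface glycoprotein mesothelin (4.78), had 0 UMIs in every control class and 717 in the colonocyte-like cells of the Mettl14_cKO library, at least 1681-fold higher against a floor of 3 counts per class. Gp2, a receptor for bacterial fimbriae (4.20), had 0 and 3551 UMIs in goblet-like cells, at least 1689-fold higher. The others were the steroid-metabolising reductase Akr1c21 (5.14), Igfals (4.93), the NADPH oxidase subunit Ncf4 (4.75), the secreted glycoprotein Lrg1 (4.27) and the chitinase Chit1 (4.11).

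The 12 lowest genes included metabolic enzymes, immune defence genes and Gsdmc4 (mean log2 ratio -3.62). Mptx1, a mucosal pentraxin and one of the goblet markers, was lowest at -4.68, with 1910 and 44.6 CPM in goblet-like cells (42.8-fold lower, 40.8 to 45.0). T or NK-like cells held 475 and 3.02 CPM of it, and after subtraction of the T or NK-like level per cell its mean was -1.87. Sult1a1, a phenol sulfotransferase and colonocyte marker (-4.49), had 403 and 24.6 CPM in colonocyte-like cells (16.3-fold lower, 13.6 to 19.9). Hao2, a hydroxyacid oxidase of peroxisomes (-3.56), had 655 and 60.3 CPM there (10.9-fold, 9.63 to 12.3). Isg15, an interferon-induced ubiquitin-like protein (-3.30), had 272 and 26.2 CPM in colonocyte-like cells (10.4-fold, 8.66 to 12.6), and the immunoproteasome gene Psmb9 (-3.13) had 139 and 10.4 CPM. The others given here, which make 11 of the 12, were the urea cycle enzyme Otc (-3.61), Bex4 (-3.21), the zinc transporter Slc39a5 (-3.19), the PCNA-binding protein Pclaf (-3.16, a cycling marker) and Tmem252 (-3.11). Otc and Bex4 lie on the X chromosome, and Bex4 shares 22.9% of its 3' words with other genes. All 24 genes kept their direction under 11 other settings, but their sizes moved. With a pseudocount of 10 CPM Msln was 2.03, Gp2 1.59 and Chit1 1.56, with the strict filter Slpi was 4.71, and with no doublets removed Pclaf was -1.62.

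Ranked within single classes, the rule named mostly the same genes. In cycling-like and goblet-like cells it added the immunoproteasome gene Psmb8, with 277 and 20.5 CPM (13.5-fold lower, 12.4 to 14.7) and 146 and 12.9 CPM (11.3-fold lower). In colonocyte-like cells it added Lce3b, with 1 and 674 UMIs (4740-fold higher, 848 to 187482), a value near the floor in the control, and the calcium-binding S100g on the X chromosome, with 3521 and 274 CPM (12.8-fold lower, 12.1 to 13.6). Enteroendocrine-like cells had 40.1 and 848 CPM of Ppy, pancreatic polypeptide (21.1-fold higher, 17.0 to 26.5). They also had 294 and 2 UMIs of Pclaf (141-fold lower, 38.8 to 1173).

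**Figure D3:**
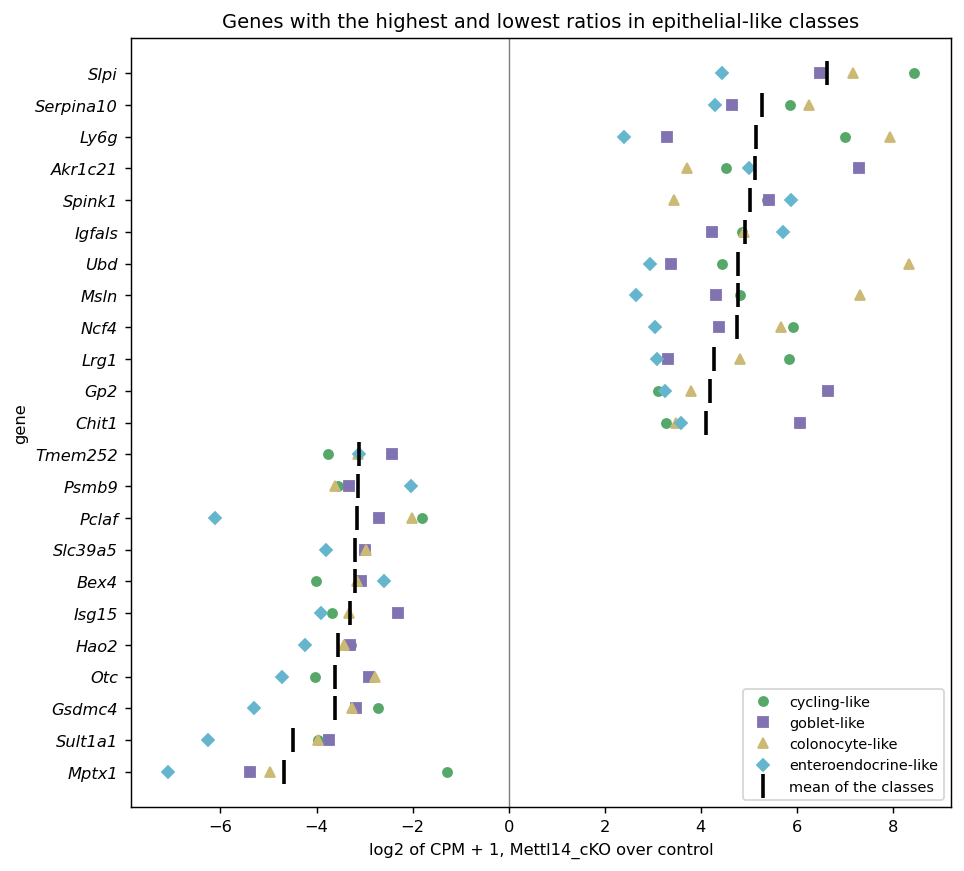
Log2 ratio of CPM plus 1, Mettl14_cKO over control, for the 12 highest and 11 of the 12 lowest genes, with a coloured mark for each of the 4 classes and a black bar for their mean. The means ran from 6.64 (Slpi) to 4.11 (Chit1) and from -4.68 (Mptx1) to -3.11 (Tmem252).

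Antigen presentation, interferon response and cell cycle lists had lower medians in the Mettl14_cKO library. All 7 MHC class II genes measured were at least 1.5-fold lower, with a median of -2.68 (H2-Ab1 -3.47, H2-DMb1 -3.30). Of 14 MHC class I genes 11 were lower, 0 higher and 3 between (median -1.35; H2-T3 -3.18, Psmb9 -3.13). Of 27 interferon response genes 22 were lower, 2 higher and 3 between (median -1.23), led by Isg15 (-3.30) and the GTPase Iigp1 (-3.30), with Ifit1bl1 highest (1.20). In cycling-like cells these 3 medians were -3.75, -1.79 and -1.48, and in enteroendocrine-like cells they were weaker, at -2.34, -0.63 (interval -1.86 to 0.58) and -0.56. Of 21 G2 and M phase genes all 21 were lower (median -1.65; Nusap1 -2.60, Hmmr -2.46), and of 21 S phase genes 17 were lower and 4 between (median -1.08; Pclaf -3.16, Clspn -1.39). Members of both cell cycle lists were markers of the cycling-like class, and within that class their medians were -0.64 and -0.49. In goblet-like cells they were -1.59 and -0.97, and in enteroendocrine-like cells -3.43 and -2.06. Goblet-like cells held 6233 Pclaf UMIs in the control and 646 in the Mettl14_cKO library, and Pclaf was among the leading genes of control-majority cluster 0. A different mix of cells within a class therefore cannot be told apart from lower levels per cell. Over the classes the medians were small under some settings. With no doublets removed they were -0.55 and -0.15, at resolution 2 -0.52 and -0.17, and with the strict filter -0.69 and -0.31. A pseudocount of 10 CPM gave -1.44 for MHC class II and -0.60 for the interferon response. All 5 lists lay at percentile 0 of the matched random lists. In T or NK-like cells the medians were 0.68 for MHC class II (4 of 7 measured, interval -0.004 to 1.11), -0.08 for class I and -0.72 for the interferon response (-1.15 to 0.30). Free RNA was not separated there: myeloid-like cells were 9 in the control and 431 in the Mettl14_cKO library, and B or plasma-like cells 6 and 197. Cluster 23 of this class held 4 control and 217 Mettl14_cKO cells, so the class also differed in make-up.

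Gene lists of metabolism split by pathway. Of 13 mitochondrially encoded genes 5 were higher, 0 lower and 8 between (median 0.44, percentile 99.98; mt-Nd3 1.42, mt-Nd1 1.18), and T or NK-like cells had a median of 0.40. The share of mitochondrial UMIs per cell had medians of 4.51% and 7.19% in cycling-like and 3.12% and 5.33% in goblet-like cells, but 2.39% and 2.38% in enteroendocrine-like cells, where the list median was 0.43. With the strict filter the list median was 0.28 (-0.20 to 0.72). Of 29 nuclear oxidative phosphorylation genes 6 were lower, 0 higher and 23 between (median -0.37, percentile 0.03; Sdhb -0.80, Cyc1 -0.71). Of 17 fatty acid oxidation genes 3 were lower, 0 higher and 14 between (median -0.46, percentile 0.25), with members such as Hadh (-0.78) and Cpt2 (0.55). Of 16 cholesterol synthesis genes 7 were lower, 0 higher and 9 between (median -0.50, percentile 0.05; Mvd -1.40, Idi1 -1.22). Of 12 glycolysis genes 4 were higher, 0 lower and 8 between (median 0.23 with an interval of -0.02 to 0.67, percentile 99.1), led by the glucose transporter gene Slc2a1 (0.96). Of 12 NRF2 targets and metallothioneins 5 were higher, 0 lower and 7 between (median 0.33, percentile 99.5), led by the metal-binding Mt2 (2.83) and the haem-degrading Hmox1 (2.09). Of 19 dissociation and immediate early genes 10 were lower, 2 higher and 7 between (median -0.78, percentile 0, with Atf3 -1.49 and Cyr61 -1.36). T or NK-like cells had medians of -0.65 for cholesterol synthesis, -0.54 for fatty acid oxidation, -0.23 for nuclear oxidative phosphorylation and 0.26 for glycolysis. The shifts of those lists were thus not particular to epithelial-like cells, though free RNA was not separated there. For NRF2 targets and dissociation genes the T or NK-like medians were 0.21 and -0.08.

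Lists of epithelial function held members in both directions. Of 17 mucus and goblet secretory genes 7 were lower, 4 higher and 6 between (median -0.46, percentile 0.1), from Ang4 (-1.64) and the mucin gene Muc2 (-1.19) to the trefoil factor gene Tff3 (2.26). That median was -0.07 within goblet-like cells (percentile 51.1), 0.82 within cycling-like and -1.19 within enteroendocrine-like cells, and 0.03 after subtraction of free RNA. Of 20 mature colonocyte genes 8 were lower, 3 higher and 9 between (median -0.43, percentile 0.17), from the protease gene Mep1a (-1.93) and the fatty acid-binding Fabp2 (-1.68) to Dhrs9, the highest, and within colonocyte-like cells the median was 0.02. Several members of both lists were markers that named these classes. Of 20 ion and water transport genes 6 were lower and 5 higher (median 0.03, percentile 68.5), from the carbonic anhydrase gene Car1 (-1.84) to the sodium channel gene Scnn1b (1.30). Car1 was -1.02 after subtraction of the T or NK-like level per cell. Of 21 antimicrobial and mucosal defence genes 9 were higher and 7 lower (median 0.18, percentile 94.9). The highest were the calprotectin genes S100a8 (5.41) and S100a9 (4.80), both neutrophil genes, and the lowest was Ido1 (-2.36). Cluster 24, with both calprotectin genes among its leading genes, held 0 control and 214 Mettl14_cKO cells. Free RNA of such cells was not told apart from epithelial RNA here. The bar on genes higher in a non-epithelial class applied to named genes, not to list members. Of 19 TNF and NF-kB targets 9 were higher and 6 lower (median 0.55, percentile 99.99; Ccl20 1.92, Cxcl2 -1.45), and after subtraction of free RNA the median was -0.02. It was 0.73 within cycling-like and 0.95 within colonocyte-like cells, but -0.11 within goblet-like and -0.75 within enteroendocrine-like cells. Of 16 tight junction and adhesion genes 4 were lower, 1 higher and 11 between (median -0.19, percentile 27.3; Cldn15 -2.32, Cldn4 1.25). Of 11 enteroendocrine hormone genes 5 were higher and 4 lower (median 0.12, percentile 85.6), and within enteroendocrine-like cells the median was 0.61.

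Lists of cell death and stress had medians near 0. The sign of the median changed under at least 1 of 12 other settings for all lists of this paragraph except the Hox and small intestine lists, and in the paragraph before for all but the mature colonocyte list. Intrinsic apoptosis genes had 3 of 20 higher, 1 lower and 16 between (median -0.13, percentile 32.3), with Bik highest (1.70). Of 16 pyroptosis and necroptosis genes 7 were lower and 2 higher (median -0.08, percentile 41.3), from the inflammasome sensor gene Nlrp6 (-2.39) to Il1b (2.13). Of 20 p53 target genes 5 were higher and 3 lower (median 0.08, percentile 86.7; Phlda3 3.05, Pmaip1 -0.98). Of 21 genes of the unfolded protein and integrated stress response 6 were higher and 3 lower (median 0.00, percentile 78.4; Trib3 2.31, Sdf2l1 -0.83). Of 7 gasdermin genes measured 3 were lower, all of the C group, Gsdma was higher (1.14) and Gsdmd was at 0.00 (median 0.00, percentile 53.3). Of 8 m6A writer genes Rbm15 was higher (1.44), Mettl3 lower (-0.66) and 6 between (median -0.02, percentile 57.2). Of 12 m6A erasers and readers 4 were higher and 1 lower (median 0.06, percentile 79.8; Igf2bp3 2.03, Hnrnpc -0.70). Of 15 fetal-like and regenerative genes 5 were higher and 3 lower (median -0.04, percentile 57.1; Msln 4.78, Clu 2.31), and within colonocyte-like cells the median was 0.74. Of 8 distal position Hox genes 3 were higher and 0 lower (median 0.54, percentile 99.1; Hoxd11 1.14). Of 9 small intestine markers 3 were higher and 0 lower (median 0.48, percentile 99.1), led by Rbp2 (1.83) and Fabp6 (1.42), the latter with 14.4 and 62.1 CPM in epithelial-like cells. The small intestine median had an interval of -0.08 to 1.42 and ran from 0.06 to 0.93 under other settings. The Hox median ran from 0.19 to 0.66. Median-of-ratios scaling put the bulk of genes at -0.12 in goblet-like and -0.18 in colonocyte-like cells, so sizes there are relative to those shifts.

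**Figure D4:**
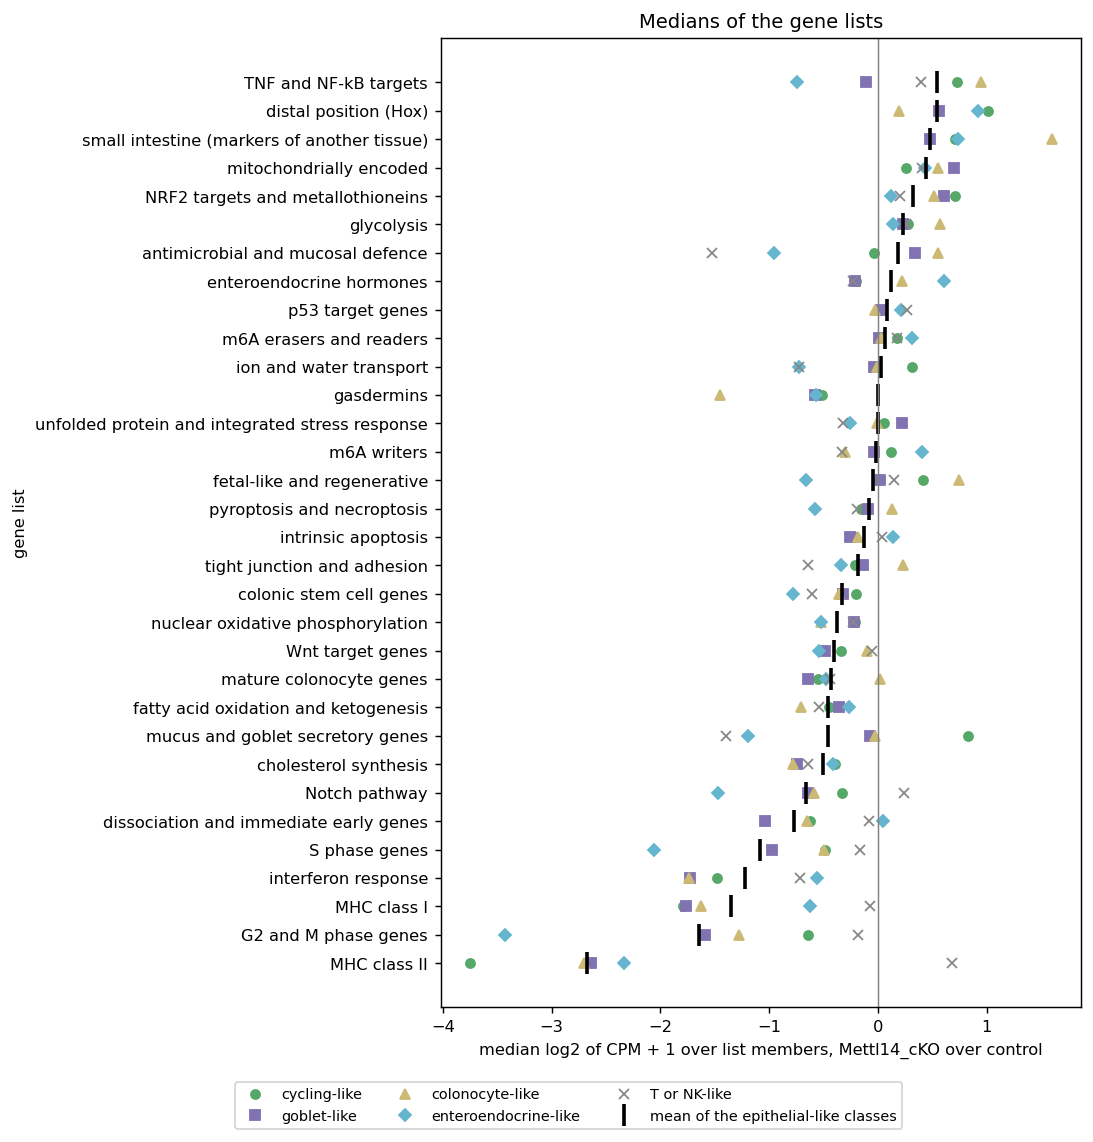
Median log2 ratio of CPM plus 1, Mettl14_cKO over control, of each of the 32 gene lists, with a coloured mark for each class with at least 3 measured members and a black bar for the list's median over the class means. MHC class II lay lowest (-2.68) and TNF and NF-kB targets highest (0.55), and the latter was -0.02 after subtraction of free RNA.

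In T or NK-like cells the rule named several genes that were abundant in epithelial-like cells of the same library. Spink1 had 27.0 and 1279 CPM (47.3-fold higher, 30.8 to 76.7), Slpi 1 and 119 UMIs, Mptx1 369 and 3 UMIs, Car1 2691 and 79.4 CPM (33.9-fold lower, 27.1 to 43.0) and Gm1123 65 and 3 UMIs. The ratios from 3 or fewer UMIs have wide intervals, 16.4 to 3700 for Slpi, 53.5 to 768 for Mptx1 and 9.09 to 138 for Gm1123. Of immune genes, the scavenger receptor gene Cd163l1 had 1 and 101 UMIs (78.8-fold higher, 13.8 to 3145) and the natural killer receptor gene Klra1 79 and 1 UMIs (101-fold lower, 17.6 to 4047). Abi3bp had 0 and 56 UMIs, at least 14.6-fold higher. Cluster 23, with 4 control and 217 Mettl14_cKO cells, held most of the difference in make-up of this class.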

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

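The tests of sex, of free RNA, of cells of low depth, of the mix of classes and both tests on cells that clustered with the control were chosen only after the result was seen. A signal in genes outside the comparisons was Xist, at 312 CPM in the Mettl14_cKO library and 0.0644 CPM in the control. In that library 5908 cells had Xist and no Y-linked UMI, and in the control 5310 cells had Y-linked UMIs and no Xist. Another signal lay in barcodes removed before the comparisons: 17.4% of deposited Mettl14_cKO barcodes (1601) and 5.84% of control barcodes (595) had 25% or more mitochondrial UMIs.

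Gene expression of epithelial-like cells differed between the libraries. Free RNA as the whole cause is argued against for most of the 457 eligible genes at least 2-fold apart. Of these, 85.8% (82.2 to 88.8) kept 50% or more of their mean log2 ratio when the whole T or NK-like level was taken off the higher library alone. Genes over 5 times higher in a non-epithelial class were not eligible, so this share says nothing about them. Free RNA stays open for those genes, for the rest of the 457, and for lists whose medians changed sign on subtraction. Those medians went to 0.03 (mucus), -0.02 (TNF), -0.04 (antimicrobial defence), -0.03 (p53 targets), -0.11 (gasdermins) and -0.29 (enteroendocrine hormones). For more cells of low depth as the cause, 100% (at least 99.2) of the 457 genes kept that much among cells with 5000 or more UMIs. There the Mettl14_cKO cells were the deeper ones (median 17211 against 13093 UMIs). Counts were summed over cells, so shallow cells weighed little in the ratios and this outcome was close to fixed in advance. It shows that the ratios were present in the deeper cells, and cannot decide further on depth. The sex of the mice as the whole cause cannot be told apart from the genotype, because each library held 1 sex by its Xist and Y-linked levels. Among Mettl14_cKO cells in control-majority clusters, gasdermin C was over 2 times that of the other cells in 1 of 3 classes. The ratios were 5.20 in colonocyte-like (4.38 to 6.16), 1.58 in goblet-like (0.945 to 2.51) and 0.926 in cycling-like cells (0.748 to 1.14). They compare cells of different clusters, such as colonocyte-like cluster 10, with Gsdmc2 and Gsdmc4 among its leading genes, against cluster 18. These ratios therefore cannot decide on sex. The loss of Mettl14 may be the cause, and a difference between animals, sexes or the handling of the 2 pools may be as well; libraries of single mice of both sexes would separate them.

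Fewer epithelial-like cells of the Mettl14_cKO library had an Lgr5 UMI. Lower depth per cell as the whole cause is argued against by the difference of -0.642 percentage points (-0.847 to -0.464) at a common depth. A different mix of cells cannot be told apart from a lower Lgr5 level per cell, because the cycling-like class held different clusters in each library: Lgr5 was 16.8-fold higher in the control over the class (9.85 to 30.9) but 2.04-fold (1.01 to 4.84) in the control-majority clusters, where the Mettl14_cKO library had 8 UMIs. Either may give this pattern, and sex was not tested for it.

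In the Mettl14_cKO library 272 epithelial-like cells lay in control-majority clusters, at a median of 19444.5 UMIs against 8109.5 in its other epithelial-like cells and 10675 in control cells of those clusters. Cells or RNA of the control library are argued against, because their Y-linked level was 0.786% of that of control cells in the same clusters (at most 1.83%) and 91.9% of them had Xist. Cells that kept an undeleted Mettl14 remain possible: their Mettl14 level was 1.45 times that of the other epithelial-like cells (1.04 to 1.98) and lay above that of control cells, at 7.09 and 4.72 CPM. Against the other cells of the same class it was 11.04 and 6.33 CPM in cycling-like and 5.97 and 3.97 in goblet-like cells, but 2.36 (2 UMIs) and 3.83 in colonocyte-like cells. This cannot be told apart from other causes, since Mettl14 tags were not lower in the library as a whole and may lie outside the deleted part. These cells had 68.5 CPM of gasdermin C, against 25.2 in the other cells and 341 in control cells of the same clusters, and they held 12 of the 22 Lgr5 UMIs.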

How the results depend on the processing

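The alternatives with at least 5000 UMIs per cell and with free RNA subtracted were added after the data were seen. Over 8 planned results, 61 of 71 alternative values kept their sign, and 5 class shares reversed. The 61 include 7 differences in stem-like share that stayed at 0 and so have no sign. All 24 named genes kept their direction in 264 of 264 values, and 327 of 372 values of the other lists kept theirs. The named genes were picked as the most extreme of the same data, so their kept direction is weak evidence. Where a value moved and no reason is given, the cause was not tested. Differences in shares below are percentage points, Mettl14_cKO minus control, against 12.9 for cycling-like, -3.97 for goblet-like and -20.9 for colonocyte-like cells.

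With no doublets removed these were 4.17, 4.763 (reversed) and -16.09, the stem cell list median went from -0.33 to 0.08977 and the Lgr5 share from -0.642 to -0.3852, a move of the random draw, since over all draws -0.575 and -0.572 were expected. The strict filter gave -16.61 (reversed), 2.421 (reversed) and -17.86. The lenient filter gave -17.38 for colonocyte-like and 16.16 for stem-like cells, and a gasdermin C log2 ratio of -3.487 in place of -3.51. Unnamed epithelial cells went the other way under it, at 16.4% in the control and 4.31% in the Mettl14_cKO library. Resolution 0.5 gave 18.30, -7.099 and -18.24. Resolution 2 gave -4.536 (reversed), 6.450 (reversed) and -14.01, with a stem cell list median of 0.07882. Naming by nearest control cells gave -1.146 for goblet-like and -15.16 for colonocyte-like cells, and 0.03877 for the stem cell list. All kept cells as denominator gave 8.818 for cycling-like and -8.073 for goblet-like cells, and cells with at least 5000 UMIs gave 16.44 and -7.106.

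Gasdermin C was -3.464 under median-of-ratios scaling, -3.465 in thinned cells and -3.160 with a pseudocount of 10 CPM, and Mettl14 went from 0.07 to -0.3164 in thinned cells (interval -0.99 to 0.20). The Lgr5 share difference was -3.104 without thinning and -0.2837 at 850 UMIs (-0.319 expected over draws). Depth limits that share, since thinning leaves few Lgr5 UMIs. No paired analysis was possible because each genotype had 1 library with its mice pooled. The planned comparison within each sex was not run, as the control library was Y-positive and the Mettl14_cKO library Xist-positive.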

Other observations

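The unnamed epithelial cells of the libraries were different clusters. Cluster 11 held 0 control and 554 Mettl14_cKO cells (7.83% of kept cells), with Il4i1, Plb1, Igf1, Ccl25 and Msln among its leading genes. Cluster 30 held 0 and 125 cells (1.77%), led by Cldn10, Clu, the chemokine gene Ccl20 and the fatty acid-binding Fabp5. Cluster 20 held 288 control (3.17%) and 3 Mettl14_cKO cells, led by Sval1, Mptx1 and Hoxb13. These genes set the clusters apart, so their levels are no separate result. Gasdermin C in unnamed epithelial cells was 318 CPM in the control, from 2039 UMIs, and 26.5-fold lower in the Mettl14_cKO library (22.1 to 32.0), from 126 UMIs, across these different clusters.

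Immune clusters of the Mettl14_cKO library were of several kinds. Cluster 24, with the neutrophil genes S100a9 and Retnlg, held 0 control and 214 Mettl14_cKO cells. Cluster 25, with the macrophage genes C1qb, Apoe and Lyz2, held 7 and 198, and cluster 33, with the mast cell genes Mcpt1, Mcpt2 and Cpa3, held 2 and 19. Cluster 26, with the plasma cell genes Igha and Jchain and the B cell genes Cd79a, Cd79b, Ebf1 and Ly6d, held 6 and 197. Of the T or NK-like clusters, 12 (Ccl5, Gzma, Cd7) held 356 and 175 cells, and 23 (Trdc, Il17a, Trdv4) held 4 and 217.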
